A study of Mus musculus with 30 samples.

How the data were processed

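The series holds 30 Affymetrix MG_U74Av2 arrays of mouse left ventricle. Per the labels, total RNA was extracted with TRI reagent, RNA of 2 animals was pooled for each sample, and biotin-labelled cRNA was hybridized. The deposited values are log2 expression per probe set, made with RMA and Affymetrix Expression Console per the submitters' processing notes; their versions and settings are not given in the sources used here. RMA commonly corrects the background, applies quantile normalization between arrays and summarises each probe set. The values bear the log2 scale out, with medians near 6.2 on every array. No scanner files were analysed here, so no detection calls were made, and no genomic coordinates are given.

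Samples were grouped by the sex, diet and genotype in their labels into 8 groups of 3 or 4 arrays. The labels call the arrays replicates of pooled RNA; p-values measure the spread between these pooled samples, not between single animals. No pair of arrays was identical (correlations between arrays 0.925 to 0.997). Probe sets were named through the platform annotation: of 12488 probe sets, 66 are Affymetrix controls; of the other 12422, 10833 had 1 gene symbol, 396 several and 1193 none. Of the named ones 10817 were found in the current gene table by Entrez number, and 0 symbols changed. Genes are named only from probe sets with 1 symbol. For the 2073 genes with several, the probe set with the highest mean over all arrays stood for the gene, which left 8251 genes.

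One limma model with a coefficient per group was fitted to all arrays (R 4.3.3, limma 3.58.1; lmFit, contrasts and eBayes; 22 residual and 6.16 prior degrees of freedom). Tests were two-sided with a Benjamini-Hochberg adjusted p threshold of 0.05 over the 8251 genes within each comparison. The comparisons were the mean effects of HCM, sex and diet over 4 strata, each effect within its 4 strata, and 3 interactions between pairs of factors. Effects within a diet, genotype or sex came from the same fit. Positive values mean higher in HCM, in females or on casein; an interaction is the HCM effect in females minus that in males, the HCM effect on casein minus that on soy, or the diet effect in females minus that in males. Similarity of effects was described by Pearson correlation across genes between strata that share no arrays. Control RNAs were compared by a two-sided permutation test with 100000 permutations.

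The lists of genes and markers (24 functional lists and 12 cell type lists) were fixed before the data were examined: hypertrophy and fetal genes, sarcomere and Z-disc, extracellular matrix, calcium handling, ion channels, adrenergic and natriuretic signalling, fatty acid oxidation, glycolysis, oxidative phosphorylation, fatty acid synthesis, cholesterol synthesis, oestrogen and steroid receptors, oxidative stress, Y-linked genes, X-inactivation genes, circadian clock, immediate-early genes, heat shock, unfolded protein response, cell cycle, proteasome, ribosomal proteins, interferon response and class II antigen presentation, and markers of macrophages, lymphocytes, red blood cells, platelets and neutrophils, endothelium, smooth muscle and pericytes, fibroblasts and epicardium, adipocytes, nerve and Schwann cells, skeletal muscle, atrium, and liver and serum proteins. Some genes stand on more than 1 list. Lists were tested with camera (preset correlation of 0.01 between genes, adjusted over the 36 lists within a comparison), beside the number of members past the gene test.

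The rule for named genes was also fixed beforehand. It took, for each mean effect, the 10 highest and 10 lowest fold changes among genes past the threshold with the same sign in all 4 strata, up to 4 genes per list with the largest change past the threshold (or up to 2 with the smallest p where none passed), and always Myh6, Myh7, Nppa, Nppb and Acta1 for HCM and Xist and the Y-linked genes for sex. Within strata it took the 3 highest and 3 lowest, and for interactions the 10 smallest p, or 3 where none passed; fewer may be named, in that order. Values on soy or in wild type alone are from the fit of all groups, or, where so stated, from the fit without the casein HCM arrays.

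Alternatives fixed beforehand were testing all probe sets, leaving out the dimmest 40% of genes, adding quantile normalization, centring each array on its median, the replicate number as a block, array weights, an intensity trend in the prior variance, fitting only the 2 groups compared, leaving out each array in turn, and camera with an estimated correlation. Chosen after seeing the data was the array set as a random block (duplicateCorrelation with statmod 1.5.0, consensus correlation 0.167). So were the set of the casein wild-type arrays as a fixed term and leaving out the casein HCM arrays. The matrix list within each set and the comparison of probe sets of the same gene were also chosen then. The share of genes with probe sets in opposite directions is set beside the share that independent signs would give, from the share of higher calls among those probe sets. The array set divides the casein wild-type arrays by the sign of BioD minus BioC and takes each other labelled combination of diet and genotype as a set.

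The steps were tested on simulated values drawn with each gene's own mean and residual spread, in 5 runs over 8251 genes with 200 changed. For the mean HCM effect 99.7% of genes changed by 0.5 (log2) were recovered, for HCM in male soy and for sex in soy wild type 80.3%, and for the interaction of diet and genotype 74.9%; at 1 the share was 99.7% or more, and false calls made up 4.21% to 5.57%. The camera test, at an unadjusted p under 0.05, found 20 of 20 lists shifted by 0.3 and called 0 unchanged lists. Simulated values were independent between genes and between arrays, without array sets. The shares of false calls and the list result therefore do not cover correlated genes or differences between array sets. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.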

Results

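Gene expression was measured in the left ventricle of C57BL/6 mice that differed in 3 factors: sex, diet and genotype. The diets were soy-based or casein-based, and the genotypes were wild type and HCM. The labels do not spell out HCM, which in cardiac genetics is the usual short form of hypertrophic cardiomyopathy, a disease in which the ventricular wall thickens, and they name no mutation. The mice were 2 months old, and each RNA sample combined 2 animals. The 30 arrays formed 8 groups: 4 arrays in each of the male and female soy wild-type, casein wild-type and casein HCM groups, and 3 arrays in each of the male and female soy HCM groups. Median log2 expression ranged from 6.11 to 6.22 between arrays. It was at most 6.188 on the casein arrays and at least 6.198 on the soy arrays. The number of arrays per group limits the precision of every value below. Errors of fold changes are standard errors.

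Exogenous control RNAs differed between arrays, largely along diet and genotype. The array sets used below were the labelled combinations of diet and genotype, with casein wild type alone divided by these controls. The 4 bacterial poly-A controls, which are added to total RNA before labelling where they are used, were higher on the 8 casein HCM arrays than on the 22 other arrays. Dap read 8.69 ± 0.27 (SD) on the casein HCM arrays and 4.42 ± 0.20 (SD) elsewhere, a log2 difference of 4.28. The differences of Thr, Lys and Phe were 2.19, 1.01 and 0.93. In each case the lowest casein HCM array lay above the highest other array (two-sided permutation test, p = 1e-05, the smallest that 100000 permutations can give). The hybridization controls BioD and BioC, added to the labelled RNA, gave a second division. BioD minus BioC averaged 0.10 on the soy wild-type arrays, 1.01 on the soy HCM arrays and 0.75 on the casein HCM arrays. The casein wild-type arrays divided into set A (1.07, replicates 1 and 2 of both sexes) and set B (-0.76, replicates 3 and 4 of both sexes). Set A (1.01 to 1.19) overlapped the soy HCM arrays (0.89 to 1.13), so BioD minus BioC did not separate those sets. Between sets A and B, which share diet and genotype and hold both sexes equally, 1029 genes passed the test (621 higher in A, 408 lower). Every set holds males and females in equal number, so a set difference shared by both sexes does not shift their comparison. The sex tests had no term for the set. Differences within sets are given for some genes and the matrix list. A difference of genotype or diet was always also a difference between sets, and for these the set entered a further fit as a random block. That fit cannot separate sets from genotype or diet, since only the casein wild-type arrays span more than 1 set. Its counts are therefore not free of differences between sets.

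**Figure D1:**
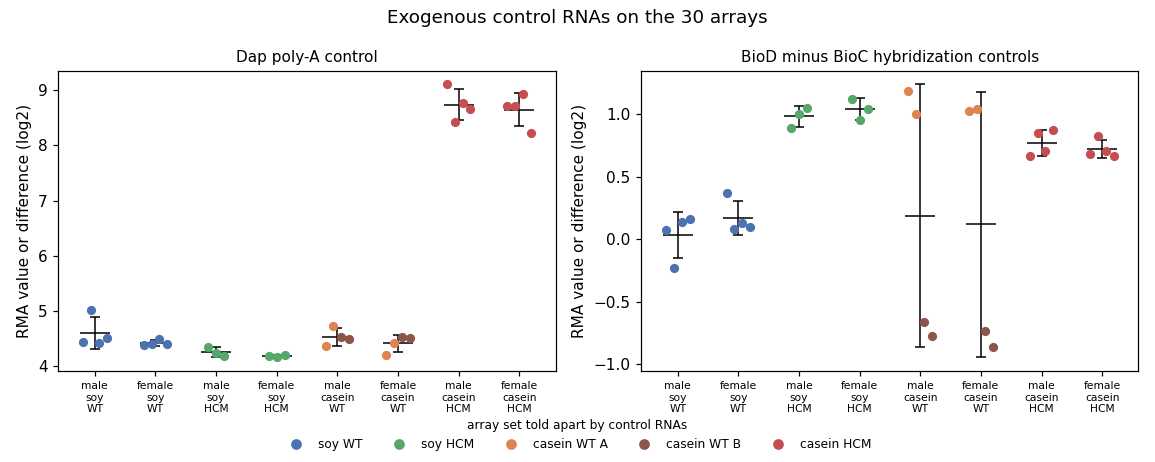
Log2 signal of the Dap poly-A control (left) and log2 difference between the BioD and BioC hybridization controls (right) on each of the 30 arrays, by group. Points are arrays, coloured by array set, and bars give the group mean and SD; Dap is at least 8.22 on the 8 casein HCM arrays and at most 5.02 on the others, and the casein wild-type arrays lie at both ends of the right-hand panel.

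The first comparison asked how HCM ventricles differed from wild-type ventricles, as the mean of the 4 combinations of sex and diet. Genes of the hypertrophic response were higher in HCM: Acta1 (skeletal alpha-actin) by 1.13 ± 0.17 on the log2 scale, Ankrd1 (a stretch-responsive ankyrin repeat protein of the sarcomere) by 1.12 ± 0.09, Nppb (the precursor of brain natriuretic peptide) by 1.10 ± 0.13 and Myh7 (the slow beta-myosin heavy chain) by 1.0 ± 0.10. Interferon-stimulated genes were also among the highest, with Ifit3 at 1.18 ± 0.06 and Ifit2 at 0.85 ± 0.07. Other genes with a large increase were Dnajb9 (a chaperone of the endoplasmic reticulum, 0.94 ± 0.07), Gas5 (0.91 ± 0.11), Ppp1cb (a catalytic subunit of protein phosphatase 1, 0.87 ± 0.13) and Enah (an actin regulator, 0.83 ± 0.10). Among genes with 1 sign in all 4 strata, the lowest fold changes were those of Ces1d (a carboxylesterase, -0.54 ± 0.07), Car14 (a carbonic anhydrase, -0.52 ± 0.05), Lrg1 (-0.49 ± 0.05), Fpgs (-0.47 ± 0.05) and Gpd1 (glycerol-3-phosphate dehydrogenase, -0.45 ± 0.04). Adjusted p in limma was 1.45e-05 or less for each of these genes. Of the 3 probe sets of Gas5, 1 passed. In all, 2814 of 8251 genes passed, 1546 higher and 1268 lower in HCM, but the fold change exceeded 1.5 in 48 of them. With the array set as a random block, 958 genes passed (588 higher, 370 lower), all of them among the 2814.

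The size of the HCM effect differed between the diets for these markers, while the direction was the same. On soy, HCM raised Ankrd1 by 0.59 ± 0.14 (adjusted p = 0.00272), Nppb by 0.77 ± 0.19 (0.00417), Myh7 by 0.70 ± 0.15 (0.00176) and Acta1 by 0.72 ± 0.25 (0.0341). On casein the same genes rose by 1.65 ± 0.13, 1.43 ± 0.18, 1.30 ± 0.14 and 1.54 ± 0.23, each with an adjusted p of 2.82e-06 or less. Ifit3 rose by 0.35 ± 0.08 on soy and 2.00 ± 0.08 on casein. Enah went the other way in size, with 1.10 ± 0.14 on soy and 0.57 ± 0.13 on casein. The heat shock protein gene Hsp90aa1 rose by 0.69 ± 0.12 on soy and 0.40 ± 0.11 on casein, a difference that did not pass (adjusted p = 0.134). The arrays with the higher poly-A control signals are the casein HCM arrays. Without them, which leaves the HCM effect on soy, 1722 genes passed (841 higher, 881 lower); of the 2814 genes, 675 passed in the same direction and 90 in the opposite one, and Acta1 (adjusted p = 0.0701), Gas5 (0.135), Ppp1cb (0.0555), Ifit2 (0.0935), Car14 (0.084) and Fpgs (0.174) no longer passed.

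**Figure D2:**
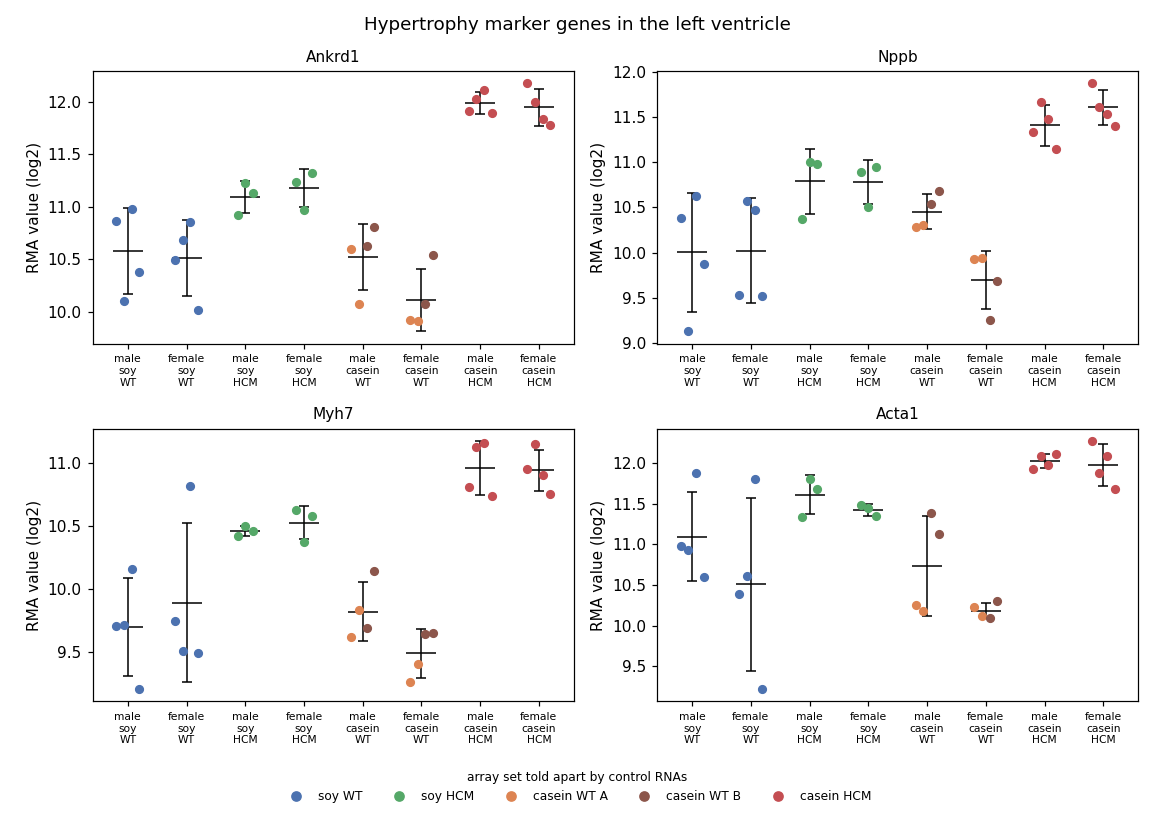
Log2 RMA expression of Ankrd1, Nppb, Myh7 and Acta1 on each array, by group; points are arrays coloured by array set, and bars give the group mean and SD. The HCM mean lies above the wild-type mean of the same sex and diet in all panels, and the 8 casein HCM arrays are the highest for Ankrd1.

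Gene lists fixed before the data were examined described the HCM effect by function. Of the hypertrophy and fetal gene list, 11 of 24 measured genes rose and 2 fell (camera, adjusted p = 0.00177; 13 and 3 adjusted over the list alone). Nppa, the atrial natriuretic peptide gene, rose by 0.46 ± 0.09 and Myh6, the fast alpha-myosin heavy chain of the adult mouse ventricle, by 0.15 ± 0.04; on soy alone Nppa was at -0.064, and with the set as a random block Myh6 did not pass (adjusted p = 0.0894). Sarcomere and Z-disc genes rose in 10 of 18 cases with none lower (0.00177), led by Myom1 (0.37 ± 0.06), Myl3 (0.29 ± 0.04), Cryab (0.28 ± 0.05) and Tnnt2 (0.25 ± 0.05). The interferon response list had 20 of 30 genes higher and none lower (2.64e-11), including Isg15 at 0.85 ± 0.08 and Ifit1 at 0.78 ± 0.08. Proteasome and muscle ubiquitin ligase genes rose in 17 of 29 cases with none lower (1.5e-06), for example Psma6 (0.53 ± 0.06) and Psma7 (0.43 ± 0.07). Ribosomal protein genes rose in 15 of 23 cases and fell in 1 (4.05e-05), with Rpl7 at 0.46 ± 0.05 and Rpl32 at 0.46 ± 0.13. Heat shock genes rose in 8 of 18 cases and fell in 2 (0.0459), led by Hspa8 (0.62 ± 0.09) and Hsp90aa1 (0.54 ± 0.08). For Cryab, Rpl7 and Hsp90aa1 a second probe set did not pass (-0.033, -0.138 and -0.015). None of these 6 lists passed with an estimated correlation between genes: the adjusted p was then 0.463 for hypertrophy, 0.678 for sarcomere and proteasome, 0.414 for interferon and ribosomal, and 0.771 for heat shock. When quantile normalization was added, the sarcomere (adjusted p = 0.201) and heat shock (0.194) lists did not pass and the other 4 did. Without the casein HCM arrays the sarcomere list passed (0.000638) and the other 5 did not; the interferon list, with 26 of 30 genes higher on casein and 3 higher on soy, then had an adjusted p of 0.175, and Isg15 was at -0.056.

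The extracellular matrix list had 11 genes higher and 11 lower of 47 in HCM, and its test did not pass (adjusted p = 0.91). Ccn2 (connective tissue growth factor) was higher by 0.69 ± 0.11, Mgp (matrix Gla protein) by 0.49 ± 0.08 and Postn (periostin) by 0.42 ± 0.14, and Col5a1 was lower by a log2 change of -0.56 ± 0.04. On soy alone Ccn2 was at -0.33, Mgp at -0.19 and Col5a1 at 0.17, and Postn did not pass. Markers of other cell types moved in part. Fibroblast and epicardial markers had 9 higher and 3 lower of 22 (adjusted p = 0.364), with Dcn at 0.39 ± 0.08 and Lum at 0.37 ± 0.08. Smooth muscle and pericyte markers had 4 higher and 1 lower of 12 (0.304), with Rgs5 at 0.74 ± 0.16 and Tagln at 0.40 ± 0.05. Endothelial markers had 5 higher and 3 lower of 16 (0.779), with Pecam1 at -0.38 ± 0.05 and Eng at -0.32 ± 0.06. Of these, Rgs5 alone passed on soy without the casein HCM arrays, where Tagln was at -0.11 and Eng at 0.038.

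For the other lists the HCM test did not pass. In muscle function, calcium handling had 7 genes higher and 4 lower of 20 (adjusted p = 0.684), including Casq1 (0.63 ± 0.09) and Slc8a1 (0.35 ± 0.10). Ion channels had 6 higher and 2 lower of 26 (0.623), and adrenergic and natriuretic signalling had 7 higher and 2 lower of 16 (0.314). In metabolism, fatty acid oxidation had 4 higher and 7 lower of 33 (0.364, but 0.00845 toward lower values with quantile normalization added), with the regulator Ppara at -0.46 ± 0.16 and Crat at -0.38 ± 0.05; Ppara was at 0.42 on soy alone. Glycolysis had 7 higher and 4 lower of 30 (0.788), oxidative phosphorylation 24 higher and 13 lower of 72 (0.623), fatty acid synthesis 2 higher and 1 lower of 13 (0.931), and cholesterol synthesis 2 higher and 1 lower of 16 (0.91). Among stress and growth lists, the unfolded protein response had 8 higher and 2 lower of 21 (0.0804), with Ddit3 at 0.52 ± 0.06 against -0.14 on soy alone. Oxidative stress genes had 7 higher and 2 lower of 31 (0.779), among them Aldh1a1 (0.67 ± 0.12; its second probe set, at -0.098, did not pass) and Nqo1 (0.44 ± 0.08). Immediate-early genes had 2 higher and 6 lower of 28 (0.508), the cell cycle 5 higher and 9 lower of 37 (0.641), and the circadian clock 2 higher and 7 lower of 18 (0.479). Oestrogen and steroid receptor genes had 4 higher and 7 lower of 22 (0.719), Y-linked genes 1 higher and 1 lower of 5 (0.788), X-inactivation genes 1 higher and 1 lower of 6 (0.931), and class II antigen presentation 1 higher and 2 lower of 12 (0.91). Among marker lists, macrophage had 2 higher and 2 lower of 24 (0.91), lymphocyte 0 and 1 of 18 (0.987), red blood cell 1 and 2 of 7 (0.728), platelet and neutrophil 0 and 3 of 13 (0.0997), and adipocyte 1 and 1 of 16 (0.623). Nerve and Schwann cell markers had 3 higher and 3 lower of 16 (0.91), skeletal muscle 7 and 4 of 21 (0.91), atrial 2 and 1 of 15 (0.623), and liver and serum protein genes 2 and 1 of 12 (0.987).

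Within single strata, HCM on soy raised Ccnd2 (cyclin D2) by 1.51 ± 0.26 in males and 1.39 ± 0.26 in females, and Odf2 by 1.40 ± 0.15 and 1.19 ± 0.15; Kcnj9 (1.33 ± 0.15) followed in males and Dnajb13 (1.20 ± 0.13) in females. The lowest on soy were Gdpd3 (-1.21 ± 0.25), Dbp (a clock output transcription factor, -1.07 ± 0.36) and Dynll2 (-1.03 ± 0.22) in males, and Dynll2 (-1.41 ± 0.22), Gdpd3 (-1.04 ± 0.25) and Tmed9 (-1.04 ± 0.14) in females. With the set as a random block Dbp (adjusted p = 0.215) and Dynll2 (0.0674) in males and Gdpd3 (0.158) in females did not pass. On casein, males with HCM had more Dbp (2.58 ± 0.34), Ifit3 (2.09 ± 0.11) and Myl7 (the atrial myosin light chain, 1.76 ± 0.48), and less Ppara (-1.57 ± 0.30), Pla2g12a (-1.36 ± 0.11) and Col5a1 (-1.31 ± 0.07). The group mean of the clock gene Arntl was 5.974 in wild type and 5.025 in HCM there. Harvest times are not given, so for Dbp in males a difference in clock phase between arrays cannot be told apart from HCM. Females with HCM on casein had more Ddit4 (1.93 ± 0.33), Ifit3 (1.91 ± 0.11) and Nppb (1.91 ± 0.25), and less Odf2 (-1.43 ± 0.14), Pla2g12a (-1.36 ± 0.11) and Kcnj9 (-1.35 ± 0.14). The second probe set of Pla2g12a passed in the opposite direction on casein, at 0.36 in males and 0.35 in females, and no other probe set of Odf2, Kcnj9, Dnajb13 or Dynll2 passed in these strata. The counts were 1111 in males on soy (598 higher, 513 lower), 339 in females on soy (173, 166), 2664 in males on casein (1502, 1162) and 2776 in females on casein (1534, 1242). With the set as a random block they were 113, 58, 1667 and 1778. On soy the counts also depended on the fit: with only the 2 groups compared they were 7 in males and 1113 in females, and with array weights 2448 and 1676, so they do not rank the sexes. The male soy count depended on single arrays: it was 249 without male soy HCM replicate 3, 329 without male soy HCM replicate 2, 521 without male soy wild-type replicate 2 and 1767 without male soy wild-type replicate 1. The female soy count rose to 666 without male soy wild-type replicate 2, through the shared spread, and lay between 111 and 224 when any one of the 7 female soy arrays was left out. Across genes, which are not independent replicates, HCM effects of males and females correlated at r = 0.77, and 745 genes passed in both sexes in the same direction with 0 in opposite ones. Both sexes lie in the same array sets, so a difference between sets enters both effects alike. This agreement therefore cannot separate HCM from the sets.

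The diet comparison asked how ventricles of mice fed casein differed from those of mice fed soy. Scd1, the stearoyl-CoA desaturase that makes monounsaturated fatty acids, had the highest mean change, 1.49 ± 0.08 on the log2 scale; it was higher on casein by 2.44 ± 0.11 in wild-type and 0.54 ± 0.12 in HCM mice. Sod1 (cytosolic superoxide dismutase) was higher by 1.43 ± 0.10, A4galt by 1.28 ± 0.12, Pcp4l1 by 1.26 ± 0.08 and Tnp1 by 1.21 ± 0.07. Kif5b (a kinesin heavy chain) was lower by a log2 change of -1.38 ± 0.14, Gtpbp1 of -1.26 ± 0.05, S100a14 of -1.16 ± 0.06 and Muc13 of -1.11 ± 0.06. Slc23a3 (1.34 ± 0.12) and Bad (-1.15 ± 0.07) had a second probe set that passed in the opposite direction, at -0.31 and 0.69. The values of Pcp4l1, Tnp1, S100a14 and Muc13 rest on 1 probe set each: the other did not pass and was at 0.131, -0.082, 0.007 and -0.059, and of the 3 probe sets of Scd1, 2 passed. In limma 5187 genes passed, 2549 higher and 2638 lower on casein, 417 of them with a fold change over 1.5. With arrays centred on their medians the balance turned to 3279 higher and 1946 lower. Before centring, the median of every casein array lay below that of every soy array. Without the dimmest 40% of genes, 1931 were higher and 1456 lower on casein, so the balance also depended on expression level. Of the 969 genes with more than 1 probe set past the threshold when all probe sets were tested, 447 (46.1%) had probe sets that passed in opposite directions. Independent signs would give 52.6%, and the cause was not tested. The same share was 30.4% (52.2% with independent signs) for the mean HCM effect, 11.6% and 23.8% for HCM in males and females on soy, 43.0% and 41.5% for HCM in males and females on casein, 41.4% (53.0%) for the interaction of diet and genotype, and 21.1% (40.8%) between sets A and B of the casein wild-type arrays. Without the casein HCM arrays, which leaves the diet effect in wild type, 3649 genes passed; 2869 of the 5187 passed in the same direction and 74 in the opposite one.

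Energy metabolism and protein turnover lists were higher on casein in the values as deposited. Log2 values were also spread more widely on most casein arrays (SD 1.752 to 1.85) than on the soy arrays (1.649 to 1.774). Several of these list results were lost with quantile normalization, which evens out the spread, as given below. They cannot be told apart from that difference in spread. Of the oxidative phosphorylation and TCA cycle genes, 55 of 72 were higher and 10 lower (camera, adjusted p = 5.09e-09), with Ndufb8 at 0.82 ± 0.05, Ndufa6 at 0.81 ± 0.09, Uqcrh at 0.78 ± 0.04 and Atp5e at 0.77 ± 0.05. Fatty acid uptake and oxidation genes were higher in 22 of 33 cases and lower in 1 (7.92e-05), with Eci1 at 0.80 ± 0.06, Acaa1a at 0.78 ± 0.08 and Fabp3 at 0.64 ± 0.05; the exception was Ppara at -0.89 ± 0.16, which was at -0.007 in wild type alone. Glycolysis genes were higher in 17 of 30 cases and lower in 3 (0.0234), including Pgam2 (0.68 ± 0.05), Hk1 (0.65 ± 0.05) and Slc2a4 (0.62 ± 0.05), whose second probe set passed at -0.26. Proteasome genes were higher in 25 of 29 cases with none lower (1.52e-08), with Psmb3 at 0.77 ± 0.05; Psme1, at 0.75 ± 0.07, had a second probe set that passed at -0.45. Ribosomal protein genes were higher in 18 of 23 cases and lower in 3 (2.07e-07), led by Rps10 (1.01 ± 0.06) and Rps7 (0.85 ± 0.05). Sarcomere genes were higher in 14 of 18 cases with none lower (6.33e-05), for example Myl3 (0.50 ± 0.04) and Ldb3 (0.45 ± 0.03). Interferon genes were higher in 18 of 30 cases and lower in 2 (0.00128), with Ifit3 at 1.15 ± 0.06, Isg15 at 1.03 ± 0.08 and Irf7 at 0.77 ± 0.07; in wild type alone that list did not pass (adjusted p = 0.658), with 3 genes higher and 1 lower. With an estimated correlation between genes none of the 7 lists passed, and the adjusted p was 0.255 for ribosomal, 0.756 for oxidative phosphorylation, fatty acid oxidation, proteasome and sarcomere, 0.883 for interferon and 0.963 for glycolysis. When quantile normalization was added, the oxidative phosphorylation (camera, adjusted p = 0.5), fatty acid oxidation (0.323) and sarcomere (0.379) lists did not pass. The glycolysis list did not pass either, with the opposite sign (0.917).

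Other genes taken from the lists moved singly with diet. Hmox1 (heme oxygenase, -0.79 ± 0.05) and Gpx1 (glutathione peroxidase, -0.78 ± 0.06) were lower on casein, as were the mitotic kinase gene Plk1 (-0.99 ± 0.04), Ccna2 (cyclin A, -0.63 ± 0.05), Edn1 (endothelin, -0.98 ± 0.06), Igf1 (-0.48 ± 0.06), the oestrogen receptor corepressor gene Nrip1 (-0.55 ± 0.09) and Lcn2 (-0.93 ± 0.05). For Plk1, Igf1 and Lcn2 1 probe set passed, and the highest of the others was at 0.108, 0.106 and 0.061. Of lipid synthesis genes besides Scd1, Gpam was higher (0.41 ± 0.07) and Elovl6 lower (-0.30 ± 0.04). The clock output genes Dbp (0.98 ± 0.18) and Nr1d1 (0.70 ± 0.10) were higher on casein in the mean of all strata; in wild type alone Dbp was at -0.21, the mean of -1.22 ± 0.34 in males and 0.81 ± 0.34 in females (adjusted p = 0.0799). S100a1, a calcium sensor of cardiac muscle, was at 1.03 ± 0.05 on its brightest probe set, and a second probe set passed at -0.25. In single strata of wild-type mice the highest fold changes were those of Kcnj9 (2.73 ± 0.14 in males, 2.36 ± 0.14 in females), Scd1 (2.68 ± 0.15, 2.20 ± 0.15) and Odf2 (2.32 ± 0.14, 2.18 ± 0.14). The other probe sets of Kcnj9, Scd1 and Odf2 did not pass in these strata. In HCM mice, Dbp (2.43 ± 0.36) and Ifit3 (2.13 ± 0.12) led in males and Tmsb10 (2.11 ± 0.13) and Dbp (1.90 ± 0.36) in females. Harvest times are not given, so for Dbp a difference in clock phase between arrays cannot be told apart from diet. Gtpbp1 (-2.16 ± 0.10) and Kif5b (-2.16 ± 0.29) were lowest in males and Xist (-2.15 ± 0.24) and Kif5b (-2.13 ± 0.29) in females. Xist was at 4.73 to 4.94 in casein HCM females and 4.74 to 4.94 in set B of the casein wild-type females. In set A, on the same diet, it was at 6.18 to 6.41, so casein alone did not go with low Xist. The counts were 3304 in male wild type (1610 higher, 1694 lower), 2061 in female wild type (930, 1131), 4069 in male HCM (2126, 1943) and 3639 in female HCM (1896, 1743). With arrays centred on their medians they were 2105 higher and 1119 lower in male wild type, 1341 and 748 in female wild type, 2497 and 1583 in male HCM and 2265 and 1439 in female HCM. The female wild-type count fell to 1142 with the set as a random block, and the male wild-type count was 1610 when only the 2 groups compared entered the fit. Diet effects correlated across genes at r = 0.86 between males and females and at r = 0.40 between wild type and HCM. The sexes share the array sets, so the first value cannot separate diet from the sets.

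The sex comparison asked how female and male ventricles differed. As a check of the labels, Xist, the RNA that silences one X chromosome in females, was higher in females by 1.56 ± 0.12, and the Y-linked genes Eif2s3y (-1.77 ± 0.10) and Uty (-0.46 ± 0.05) were lower; the Y-linked Kdm5d was at -0.09 ± 0.03 and did not pass (adjusted p = 0.403). Kdm6a (0.59 ± 0.08) and Eif2s3x (0.54 ± 0.05), which escape X inactivation, were higher in females. Apart from sex chromosome genes, female ventricles had more transcript of matrix genes: Lum (the proteoglycan lumican) by 0.68 ± 0.08, Mgp by 0.44 ± 0.08, Col15a1 by 0.36 ± 0.08, Smoc2 by 0.33 ± 0.06, Col6a3 by 0.31 ± 0.06 and Col6a1 by 0.27 ± 0.04. Males had more of Hsd11b1 (which regenerates active glucocorticoid, -0.40 ± 0.05), Dpep1 (-0.43 ± 0.08), Inmt (-0.42 ± 0.08) and Cpxm2 (-0.39 ± 0.07). In total 22 genes passed, 15 higher and 7 lower in females, and 744 had an unadjusted p under 0.05; with array weights 83 passed, 39 higher and 44 lower. Of these genes Col15a1 (adjusted p = 0.0449) and Erdr1 (0.74 ± 0.16, adjusted p = 0.0379) were near the threshold. Col15a1 did not pass without any of 23 single arrays, nor Erdr1 without any of 19; the second probe sets of Erdr1 (0.017) and Col6a1 (0.194) did not pass.

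Within the 5 array sets, the female minus male difference ranged from 0.55 to 1.0 for Lum and from 0.22 to 0.56 for Mgp; the genes named here were picked for having 1 sign in all 4 strata, so their signs within sets are not a separate test. Over all 47 measured extracellular matrix genes, with no member picked by its result, the difference was above 0 for 33 in soy wild type, 36 in soy HCM, 35 and 32 in sets A and B of casein wild type and 34 in casein HCM, with medians of 0.073 to 0.15. Of all genes 45.3% to 51.6% were above 0. This list was chosen for the look within sets after the data were seen, and its members are not independent. The counts describe the same arrays as the list test and are not a separate test. As a list, extracellular matrix genes were higher in 6 of 47 cases with none lower, or 13 adjusted over the list alone (camera, adjusted p = 1.33e-12), and the list passed with an estimated correlation (adjusted p = 0.0456). The X-inactivation list (3 of 6 higher, 8.56e-10) and the Y-linked list (2 of 5 lower, 4.19e-09) passed in both tests, each at 4.29e-05 with an estimated correlation. Of the fibroblast and epicardial markers, which include Lum, 1 of 22 was higher, or 4 over the list alone (0.0104); with an estimated correlation the list did not pass (adjusted p = 0.191). Interferon (7.1e-05), ribosomal (0.00381), endothelial (0.00702), heat shock and oxidative stress (0.0165 each), hypertrophy (0.0201) and atrial (0.0452) lists passed toward females with the preset correlation, with no single member past the threshold over all genes; with an estimated correlation their adjusted p lay between 0.147 and 0.611. Without the casein HCM arrays 12 genes passed, all among the 22; Col15a1 (adjusted p = 0.228), Col6a3 (0.0532), Col6a1 (0.106), Dpep1 (0.0712) and Cpxm2 (0.0532) did not. Xist itself differed between sets among females. Its value was 5.80 to 6.42 in soy wild-type females, 6.53 to 7.17 in soy HCM females, 6.18 to 6.41 in set A and 4.74 to 4.94 in set B of the casein wild-type females, and 4.73 to 4.94 in casein HCM females; no male array exceeded 4.47.

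**Figure D3:**
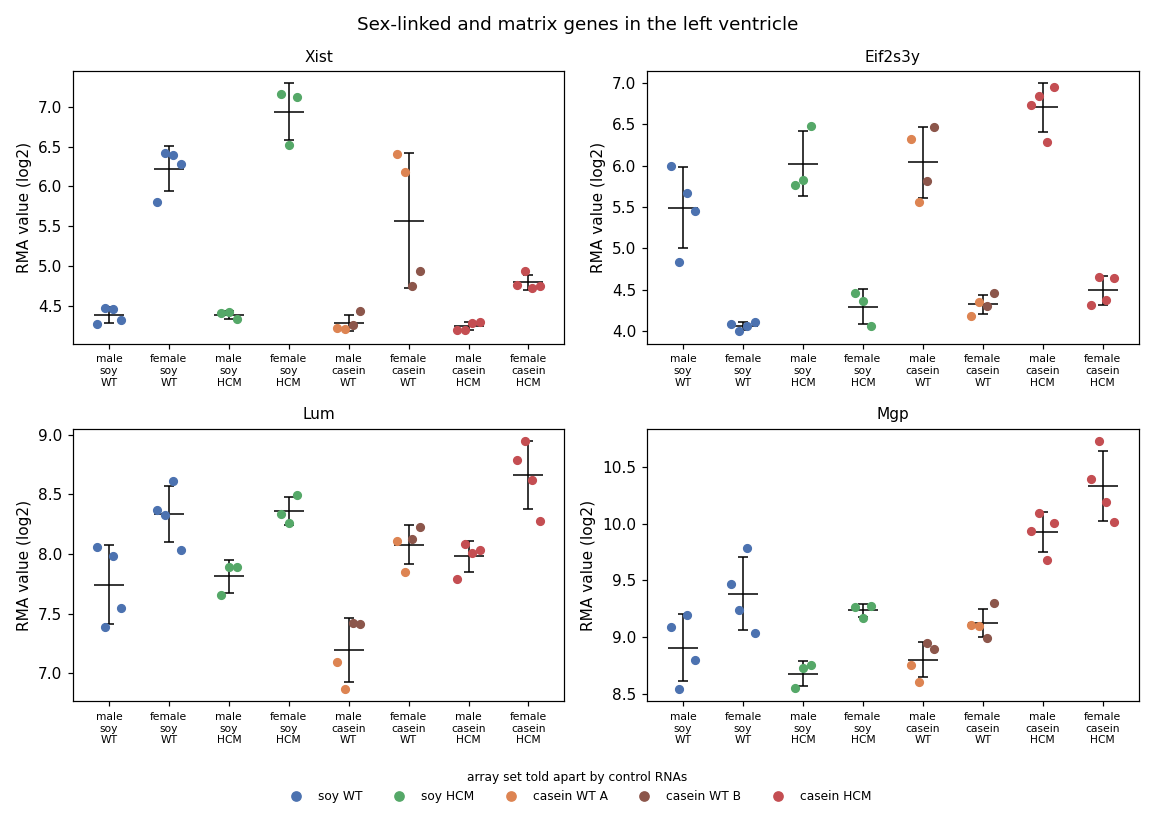
Log2 RMA expression of Xist, Eif2s3y, Lum and Mgp on each array, by group; points are arrays coloured by array set, and bars give the group mean and SD. Female means exceed male means of the same diet and genotype for Lum and Mgp, and the females of set B and of the casein HCM group have Xist values of at most 4.94.

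Within strata, few genes differed between the sexes. In soy wild type 6 genes passed: Xist (1.85 ± 0.23), Eif2s3x (0.65 ± 0.10) and Cp (ceruloplasmin, 0.56 ± 0.11) were higher in females, and Eif2s3y (-1.42 ± 0.20), Uty (-0.51 ± 0.10) and Hsd11b1 (-0.49 ± 0.10) lower. In soy HCM 3 passed: Xist (2.56 ± 0.26), Eif2s3y (-1.72 ± 0.23) and Uty (-0.66 ± 0.12). In casein wild type 12 passed (8 higher, 4 lower); besides Xist (1.28 ± 0.23) and Eif2s3y (-1.71 ± 0.20) these included the clock genes Dbp (1.67 ± 0.34), Nr1d2 (1.06 ± 0.21) and Arntl (-0.83 ± 0.18). In casein HCM 40 passed (12 higher, 28 lower), with Lum (0.68 ± 0.15), Gtpbp1 (0.58 ± 0.10) and Eif2s3x (0.54 ± 0.10) highest and Eif2s3y (-2.21 ± 0.20), Ppm1b (-0.61 ± 0.13) and Dnajb13 (-0.52 ± 0.12) lowest; no other probe set of Gtpbp1, Ppm1b or Dnajb13 passed. The unadjusted p was under 0.05 for 1520, 60, 520 and 1115 genes. The casein HCM count was 330 with array weights, 221 with only these 2 groups in the fit and 93 with the set as a random block; in soy wild type the first 2 of these fits gave 11 and 1 genes, and in soy HCM 7 and 5. These small counts also moved with single arrays. The soy wild-type count was 11 without male soy wild-type replicate 1 and 3 without male replicate 4 or female replicate 2 of that group. The casein wild-type count was 7 without male casein wild-type replicate 1, 3 or 4 or female replicate 4, 6 without female replicate 3 and 5 without female replicate 1. The casein HCM count was 3, 4 and 20 without male casein HCM replicates 2, 3 and 4, and 10, 24, 5 and 12 without female casein HCM replicates 1 to 4. It was also 21 without male soy HCM replicate 2 and 168 without male soy wild-type replicate 2.

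Interactions tested whether one factor changed the effect of another. For diet and genotype 3718 genes passed, 2060 with a higher and 1658 with a lower HCM effect on casein than on soy, and 949 differed by more than 1.5-fold. The genes with the smallest p were Cggbp1 (-2.00 ± 0.10), Col5a1 (-1.46 ± 0.07), Odf2 (-2.52 ± 0.14), Dnajb13 (-2.10 ± 0.12), Pla2g12a (-1.88 ± 0.11), Lat2 (-1.88 ± 0.12), Kcnj9 (-2.37 ± 0.15), Sac3d1 (1.55 ± 0.10), Ifit3 (1.65 ± 0.11) and Lmbr1l (-1.36 ± 0.09); Pla2g12a and Lmbr1l had a second probe set that passed in the opposite direction, and no other probe set passed for Col5a1 (-0.13), Odf2 (at most 0.034), Dnajb13 (0.112), Lat2 (-0.12) and Kcnj9 (-0.29), whose interactions therefore rest on 1 probe set. By list, interferon genes had a higher HCM effect on casein in 19 of 30 cases and a lower one in 2 (adjusted p = 8.5e-05), ribosomal protein genes in 12 of 23 with none lower (0.00199), and proteasome genes in 14 of 29 with none lower (0.003). None of the 3 passed with an estimated correlation (adjusted p = 0.83 for each). Of the genes past the threshold for HCM on each diet (2063 on soy, 4093 on casein), 313 went the same way and 827 opposite ways, where independent lists would give 511 and 512.4; the effects correlated across genes at r = -0.17. With the set as a random block 1867 genes passed, but sets and groups cannot be told apart for this interaction, since only the casein wild-type arrays span more than 1 set.

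**Figure D4:**
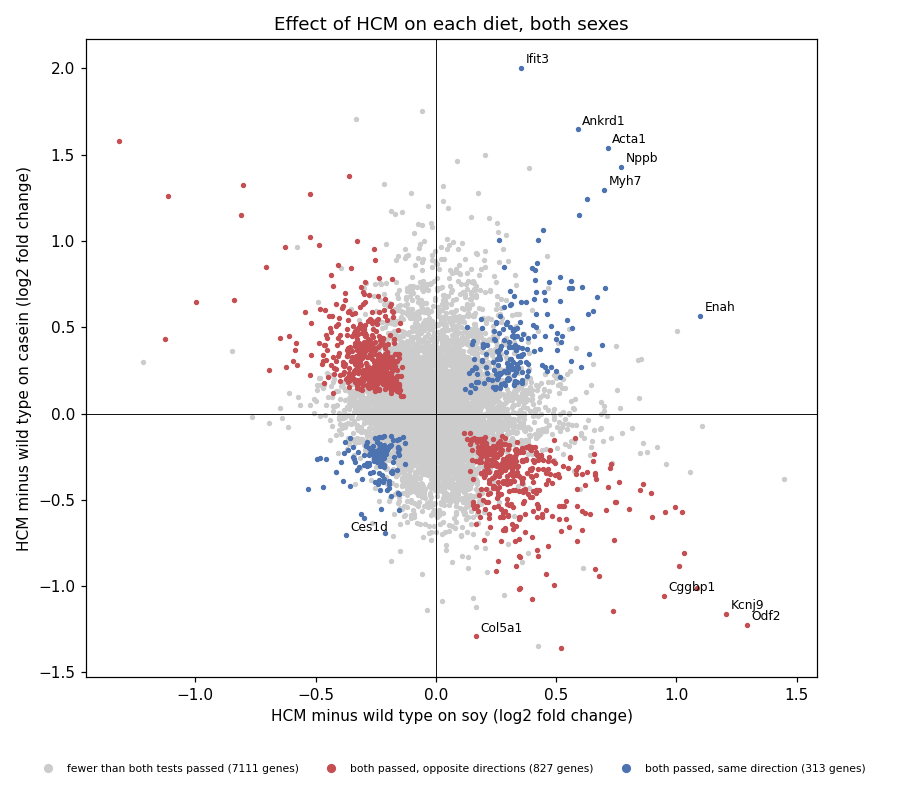
Log2 fold change of HCM over wild type on soy (horizontal axis) and on casein (vertical axis) for each of the 8251 genes, both sexes together. Blue points passed on both diets in the same direction (313 genes) and red points in opposite directions (827); the hypertrophy genes Ankrd1, Nppb, Myh7 and Acta1 lie at the upper right.

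No gene passed for the interaction of sex and genotype in limma, and 345 had an unadjusted p under 0.05. Of the genes with the smallest p, Ulk1 (an autophagy kinase) was at -0.41 ± 0.08 and the nuclear receptor Nr1d2 at -1.11 ± 0.22 (adjusted p = 0.0903 each), and Synj2 at -0.35 ± 0.08 (0.651). The circadian clock list passed as a whole (camera, adjusted p = 1.09e-06, and 0.0104 with an estimated correlation), with 3 of 18 genes higher and 9 lower when adjusted over the list alone. Dbp, at -1.36 ± 0.35, and Arntl, at 0.68 ± 0.19, were chosen from that list after their values were seen. These values average both diets. On soy the group mean of Dbp fell with HCM in both sexes, from 6.785 to 5.710 in males and 6.429 to 5.279 in females. On casein it rose from 5.563 to 8.142 in males and was 7.237 and 7.176 in females. Arntl rose on soy in both sexes, and on casein fell in males (5.974 to 5.025) and rose in females (5.140 to 5.378). The glycolysis (0.0127) and proteasome (0.032) lists passed with the preset correlation only (adjusted p = 0.869 for both with an estimated one). For sex and diet no gene passed either, with 1227 at an unadjusted p under 0.05; with array weights 142 genes passed, 53 higher and 89 lower. Xist (-1.28 ± 0.24, adjusted p = 0.0631), Lcn2 (0.48 ± 0.10, 0.168) and Myzap (-0.54 ± 0.12, 0.168) had the smallest p, and Xist was the 1 gene that passed with the set as a random block. Its female minus male difference was 1.85 in soy wild type and 2.56 in soy HCM. On casein it was 2.08 in set A but 0.49 in set B of wild type, and 0.55 in HCM. Such a difference between sets in females alone is not removed by the block. The lists of fatty acid oxidation (2.28e-06), proteasome (7.35e-05), oxidative phosphorylation (0.000613), glycolysis (0.000815), sarcomere (0.0139) and smooth muscle (0.049) genes had a smaller diet effect in females. Those of nerve (0.00298), cell cycle (0.00403), platelet and neutrophil (0.0223), circadian clock (0.0257), lymphocyte (0.0354) and liver (0.049) genes had a higher one. None passed with an estimated correlation, where the lowest adjusted p was 0.369.

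**Figure D5:**
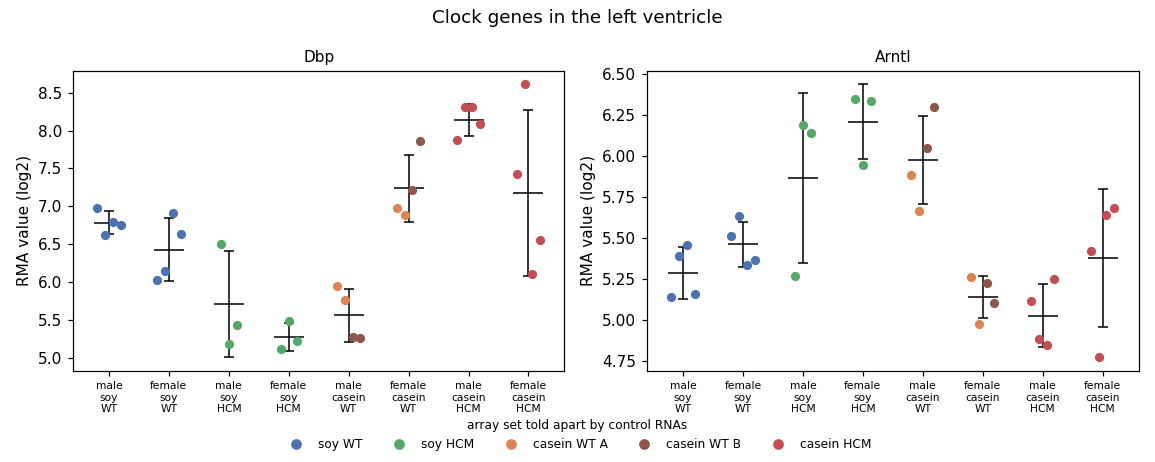
Log2 RMA expression of the clock genes Dbp and Arntl on each array, by group; points are arrays coloured by array set, and bars give the group mean and SD. Group means of Dbp run from 5.28 in female soy HCM to 8.14 in male casein HCM, and Arntl tends to be low where Dbp is high.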

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

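The tests of poly-A controls, array sets, degraded RNA, signal range and clock phase, and the counts of other splits, were chosen only after the results were seen; the test of male soy wild-type replicate 2 as a sample of another group was chosen before.

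In groups of 4 arrays, 5 of 78 tests flagged 1 array as apart from the other 3, where chance gives about 1 in 20, or 3.9. They were the spread of log2 values of female casein HCM replicate 4 (SD 1.80), the mean correlation with its own group of male soy wild-type replicate 2 (0.962) and male casein HCM replicate 4 (0.996), BioD minus BioC of female soy wild-type replicate 1 (0.37), and Xist of female casein HCM replicate 2 (4.94). The correlations were tested at 3 decimals, where the other male casein HCM arrays all read 0.995. The flag on male casein HCM replicate 4 can therefore come from rounding alone.

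Male soy wild-type replicate 2 differed from its group by more than 1 (log2) in 293 genes. Degraded RNA is argued against: the 3' minus 5' difference of Gapdh and beta-actin was 0.037, within the range of the other arrays (-0.28 to 0.31). Expression level explained 11.4% of the variance of its deviations, which argues against a compressed signal range as the whole cause, but its SD (1.65, other arrays 1.72 or more) and interquartile range (2.37, others 2.48 or more) were the lowest of the 30 arrays and the slope of its deviations on level was -0.091, so some compression stays open. A sample of another group stays open too: its mean correlation was higher with its own group than with the next, female soy wild type, by only 0.0085, within the spread of single arrays (0.958 to 0.968 with its own group, up to 0.962 with others), and of the sex markers its Eif2s3y (4.84) was the lowest of the males (others 5.45 or more; females up to 4.66) and its Xist (4.47) the highest of the males (females 4.73 or more). What set it apart was not settled, and no biological explanation was tested.

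The HCM effect differed between diets in 3718 genes by the test of the interaction. The genes with the smallest p were Cggbp1 (-2.00), Col5a1 (-1.46), Odf2 (-2.52), Dnajb13 (-2.10), Pla2g12a (-1.88), Lat2 (-1.88), Kcnj9 (-2.37), Sac3d1 (1.55), Ifit3 (1.65) and Lmbr1l (-1.36). Of the hypertrophy markers, Myh6 (-0.24), Myh7 (0.60), Nppa (1.05), Nppb (0.66) and Acta1 (0.83) also differed. In data outside the gene comparisons, the poly-A controls were higher on the casein HCM arrays than on the other arrays by 4.28 (Dap), 1.01 (Lys), 0.93 (Phe) and 2.19 (Thr).

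No tested technical explanation of the interaction of diet and genotype was excluded. The casein HCM RNA may have been prepared differently: the median difference over the 4 poly-A controls was 1.60. Values may also differ between array sets, since 1029 genes passed between the 2 sets of casein wild-type arrays. Of these genes 49.5% passed for the interaction, against 44.4% of the others. A response to HCM that depends on diet cannot be told apart from these: 1867 genes passed with the set as a random block, but the sets follow diet and genotype.

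In the interaction of sex and genotype, the median of the output genes of the clock minus that of its ROR element genes was -0.87. The interaction averages both diets, and for Dbp and Arntl the difference between the sexes lay mostly on casein. The value was below 0 for 8 of 9 output genes and above 0 for 4 of 5 ROR element genes, by sign alone, since no clock gene passed over all genes; those with small values include Per3 (-0.105) and Npas2 (0.058). Within groups, deviations of Dbp and Arntl correlated at r = -0.80 (permutation p = 0.00018, n = 30; Spearman rho = -0.71, p = 0.00049), and at r = -0.74 without female casein HCM replicates 2 and 3. A candidate explanation is therefore that arrays differ in clock phase, as with another time of day at harvest, and harvest times are not given in the sources used here. An effect of HCM on clock genes that depends on sex cannot be told apart from it, although the clock list passed (adjusted p = 0.01 with an estimated correlation).

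Other splits of the same arrays into groups of the same sizes were counted, 100 drawn for means and interactions. They treat arrays as exchangeable, so for HCM and diet they address chance among arrays and not a difference between array sets, which alone gave 1029 genes between sets A and B. Chance among arrays could be excluded for the mean effects of HCM (1 of 100 splits as large, 2814 genes, highest other 905), sex (2 of 100, 22 genes, highest other 27) and diet (1 of 100, 5187, 2597). With 1 of 35 splits as large it could also be excluded for HCM in male casein (2664; 27), female soy (339; 17) and female casein (2776; 2), for sex in casein HCM (40; 2), and for diet in male wild type (3304; 2702), male HCM (4069; 2683), female wild type (2061; 81) and female HCM (3639; 2155). It could not be excluded for HCM in male soy (3 of 35; 1111 genes, highest other 1481), sex in soy wild type (2 of 35; 6, 77) or sex in casein wild type (3 of 35; 12, 1010). The split with 1481 genes set all male soy HCM arrays and wild-type replicate 1 against wild-type replicates 2 to 4. It thus kept most of the real difference with the labels swapped. So did the splits with 2702, 2683 and 2155 genes for diet. The split with 1010 genes followed the 2 array sets, a structure of the samples. The split with 77 genes set male replicate 1 and female replicates 1 to 3 of soy wild type against the others; it follows no known set. For sex with genotype (0 genes in limma, 345 at an unadjusted p under 0.05) and sex with diet (0, 1227), all 100 splits were as large by construction, since the real count was 0, so this says nothing about chance; other splits gave up to 827 and 1689 genes. For sex in soy HCM (1 of 10; 3 genes, highest other 0) the splits are too few for a share under 0.05.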

How the results depend on the processing

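The alternatives chosen after seeing the data were the array set as a random block, the casein wild-type set as a fixed term and leaving out the casein HCM arrays. Where no cause is named below, the cause was not tested.

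With an intensity trend in the prior variance and with the replicate number as a block, every count of genes stayed within 1.5 times its value; the block gave 2669 (HCM), 21 (sex), 5151 (diet) and 3660 (diet with genotype). Across groups, 99 pairs with the same replicate number had a mean correlation of deviations of -0.002 (other pairs 0.004), with 25 over 0.1; in casein wild type the number does follow the array sets A and B. Of 204 named gene results, the side of the threshold was the same in 204 with the trend, 199 with the block, 201 with all probe sets, 200 with array weights, 199 with quantile normalization, 197 with median centring, 203 with the fixed term and 195 with the random block. Fitting only the 2 groups compared, 57 were the same and 11 lost the threshold; leaving out 1 array at a time, 5953 were the same, 147 lost it and 20 gained it. Leaving out the dimmest genes, 176 were the same and the other named genes were not tested.

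With the set as a random block the counts were 958 (HCM), 113 (male soy), 1667 (male casein), 58 (female soy), 1778 (female casein), 93 (sex in casein HCM), 1142 (diet in female wild type), 1867 (diet with genotype) and 1 (sex with diet). The fixed term gave 553 for HCM in female soy, 124 for sex in casein HCM and 1 for sex with diet.

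Without the casein HCM arrays, which leaves fewer samples and HCM on soy alone, the counts were 1722 (HCM) and 12 (sex), and 1 list passed for HCM. The sign changed, whether or not the new value passed, for the ribosomal list (camera, adjusted p = 0.984) and Nppa (-0.064), Ccn2 (-0.33), Col5a1 (0.17), Mgp (-0.19), Ddit3 (-0.14), Isg15 (-0.056), Ppara (0.42), Tagln (-0.11) and Eng (0.038) for HCM, and Dbp (-0.21) for diet. For the ribosomal list, with a median of -0.003 on soy, and for values near 0 this is no opposite effect. Of the other named results 79 were the same and 29 lost the threshold.

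Array weights gave 83 (sex), 2448 (male soy HCM), 1676 (female soy HCM), 11, 7 and 330 (sex in soy wild type, soy HCM and casein HCM) and 142 (sex with diet). Leaving out the dimmest 40% of genes, so fewer tested, gave 3387 (diet, 1931 higher and 1456 lower), 3, 0 and 87 (sex in soy wild type, soy HCM and casein HCM) and 2464 (diet with genotype). The 0 in soy HCM is from limma, against 60 genes at an unadjusted p under 0.05 over all genes; the 3 genes that passed there, Xist, Eif2s3y and Uty, were themselves among the dim genes left out. Median centring gave 3 (sex in soy wild type) and 1 (sex with diet). It moved the diet effect to 3279 higher and 1946 lower, from 2549 and 2638, with a shift toward higher in each of the 4 diet strata. Centring removes the lower array medians on casein. All probe sets gave 69 (sex in casein HCM) and 5616 (diet with genotype), with more tested. Fitting only the 2 groups compared gave 7 (male soy HCM), 1113 (female soy HCM), 1, 5 and 221 (sex in soy wild type, soy HCM and casein HCM) and 1610 (diet in male wild type).

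Quantile normalization gave 24 for sex in casein HCM. With it 3, 1 and 6 lists passed for diet, sex with genotype and sex with diet, and glycolysis changed sign for diet without passing (camera, adjusted p = 0.917). With an estimated correlation 0 lists passed for HCM, 3 for sex, 0 for diet, 1 for sex with genotype, 0 for diet with genotype and 0 for sex with diet.

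Leaving out each array gave 2389 to 2994 (HCM), 16 to 33 (sex), 5001 to 5530 (diet), 249 to 1767 (HCM male soy), 2184 to 3238 (male casein), 111 to 666 (female soy), 2354 to 3303 (female casein), 3 to 11, 2 to 3, 5 to 18 and 3 to 168 (sex in soy wild type, soy HCM, casein wild type and casein HCM), 2612 to 3578, 3466 to 4578, 1541 to 2657 and 2973 to 4154 (diet in male wild type, male HCM, female wild type and female HCM), 0 to 4 (sex with genotype, 4 without female casein HCM replicate 2), 3472 to 4090 (diet with genotype) and 0 to 9 (sex with diet, 9 without male soy wild-type replicate 1). Correlations of effects ranged from -0.24 to -0.13 (HCM, soy and casein), 0.38 to 0.42 (diet, wild type and HCM), 0.16 to 0.36 (sex, wild type and HCM), 0.73 to 0.82 (HCM, sexes), 0.84 to 0.91 (diet, sexes) and -0.20 to 0.06 (sex, soy and casein). Signal over background was not measured apart from the dim filter.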
